A study of Mus musculus with 15 samples.

How the data were processed

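RNA from 15 whole mouse aortas was measured on Affymetrix mouse expression arrays, 1 array per mouse, per the labels' protocols. The deposited values are log2 levels that the authors made with RMA, per the submitters' processing notes; the notes name no version and leave open whether the 15 arrays were normalized in 1 run or by group. The medians of the 15 arrays spanned 4.35 to 4.42, and pairwise correlations 0.972 to 0.997. The values were used as deposited. For arrays no depth applies, and their number limits the precision.

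Groups were taken from the labels as given. Apoe null mice came from a commercial supplier and Apoe/RAGE null mice from another laboratory's colony, per the labels' protocols, so genotype and colony cannot be separated. One non-diabetic Apoe/RAGE null sample was lost before hybridization, per the submitters' processing notes. The table had 45101 probe sets, of which 64 control probe sets were left out and 45037 tested. Of these, 34945 carried 1 gene, 932 several and 9160 none that was named here. Names came from the array annotation of 2016, and 34741 of the probe sets with 1 gene matched by Entrez ID a reference gene table used for names and for which genes neighbour each other (assembly GRCm38.p6). For gene-level results the probe set with the highest mean over all 15 arrays stood for each of 18193 genes.

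Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 15 arrays in the fit, empirical Bayes moderation and Benjamini-Hochberg adjustment over all probe sets at 0.05. The comparisons were diabetes in each genotype, RAGE deletion in each disease state, and their interaction. Lists of genes, 35 in all, were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of each comparison; that of RAGE ligands was written with the study's interest in mind. Results for 1 of the lists and 1 gene are not reported here, though the list stays in the counts of lists. "Adjusted over the list alone" means that the limma p-values of a list's members were adjusted among themselves. The comparisons, tests, lists, rule for named genes and most alternatives were fixed before the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

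Genes were named by rule. Among genes with an adjusted p under 0.05 and non-overlapping groups, the 12 with the largest positive and the 12 with the largest negative fold change were eligible. Where fewer than 5 passed in a direction, the genes with the smallest p were added up to 5. Ager, Apoe and the 4 members with the smallest p of each list were also eligible, and provisional symbols were skipped. The 6 plotted genes near Ager as a set fall outside the rule and were chosen after their values were seen.

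The fit was tested on simulated data with 200 of 45037 probe sets changed, in 5 draws. For RAGE deletion in diabetic aorta it recovered 36.7%, 84.8% and 96.7% of changes of 0.5, 1 and 2 (log2), with 6.80% of its calls false. For RAGE deletion in non-diabetic aorta the shares were 35.2%, 85.1% and 96.1%, with 5.14% false. A list shifted by 0.3 was found in 5 of 5 draws in both, and over the draws 1 unshifted list was called without and 0 with diabetes. The simulated noise was independent between probe sets. These shares therefore do not cover the correlation between genes in the real arrays, on which the list tests depend.

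Alternatives were the submitters' threshold of B above 0, only the compared groups in the fit, the dimmer probe sets left out, quantile normalization, median centring, a trended robust variance, array weights, 1 probe set per gene, probe sets that can share probes left out, and each array left out in turn. Lists were also tested with an estimated correlation, with fry and on all probe sets. Chosen after the data were seen were leaving out the 2 arrays least like the rest, leaving out diabetic Apoe/RAGE null replicates 9 and 10, tissue scores as covariates, and B above 0 for opposite changes. Correlations of fold changes were counted as moved when they changed by more than the jackknife spread over arrays left out. No array was left out of the values in the report unless stated.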

Results

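Gene expression was measured in the whole aorta, from the root to the bifurcation, of male C57BL/6 mice aged 9 weeks. All mice lacked apolipoprotein E (Apoe), a lipid carrier whose loss raises plasma cholesterol and leads to atherosclerosis. Some also lacked RAGE, the receptor for advanced glycation end products, which is encoded by Ager. Diabetes was induced at 6 weeks of age with 5 daily injections of streptozotocin at 65 mg/kg, a compound toxic to pancreatic beta cells, and the other mice received buffer. The 15 arrays, one per mouse, comprised 4 diabetic Apoe null, 4 non-diabetic Apoe null, 4 diabetic Apoe/RAGE null and 3 non-diabetic Apoe/RAGE null aortas. The replicate numbers run from 1 to 15 over the series and pair no mice. The number of arrays limits the precision of every value below, and p-values reflect the spread between the mice as labelled.

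The targeted gene was examined first. One Ager probe set lay between 3.08 and 3.66 (log2) on all 15 arrays. The other was higher, not lower, in the arrays labelled RAGE null. Its level was 4.42 ± 0.20 (SD, n = 4) in diabetic Apoe null and 4.60 ± 0.11 (SD, n = 4) in non-diabetic Apoe null aortas. It was 4.97 ± 0.11 (SD, n = 3) in non-diabetic aortas labelled Apoe/RAGE null. In the 4 diabetic aortas labelled Apoe/RAGE null it read 4.63 in replicate 9, 4.48 in replicate 10, 5.36 in replicate 11 and 4.95 in replicate 12. Neither difference passed the limma test (adjusted p = 1 without diabetes and 0.215 with diabetes). Whether either probe set lies in the deleted part was not given in the sources used here, so Ager does not check the genotype and the groups rest on the labels. The 1 Apoe probe set does not check that genotype either, as every group was Apoe null.

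Genes near Ager gave a second view of the genotype, and 6 of them, chosen after their values were seen, are plotted per array. In Decr2, a peroxisomal reductase gene, the 8 arrays labelled Apoe null lay between 5.32 and 6.01, and the 3 non-diabetic arrays labelled Apoe/RAGE null between 6.84 and 6.98. Of the diabetic arrays labelled Apoe/RAGE null, replicates 11 and 12 read 7.40 and 7.56, whereas replicates 9 and 10 read 5.19 and 5.10. Zfp52, Eme2, Rnf5, Polh and Cyp39a1 placed these arrays in the same way, with replicates 9 and 10 nearer to the Apoe null arrays and replicates 11 and 12 nearer to the non-diabetic Apoe/RAGE null arrays, except that Cyp39a1 in replicate 11 (5.39) lay between the groups. The probe set used differed between the non-diabetic genotypes in the same direction as 2 of 3 for Eme2 but as 1 of 4, itself alone, for Polh. Every comparison that uses the diabetic Apoe/RAGE null group therefore compares arrays as labelled, and its counts of probe sets and of lists without replicates 9 and 10 are given beside it.

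**Figure D1:**
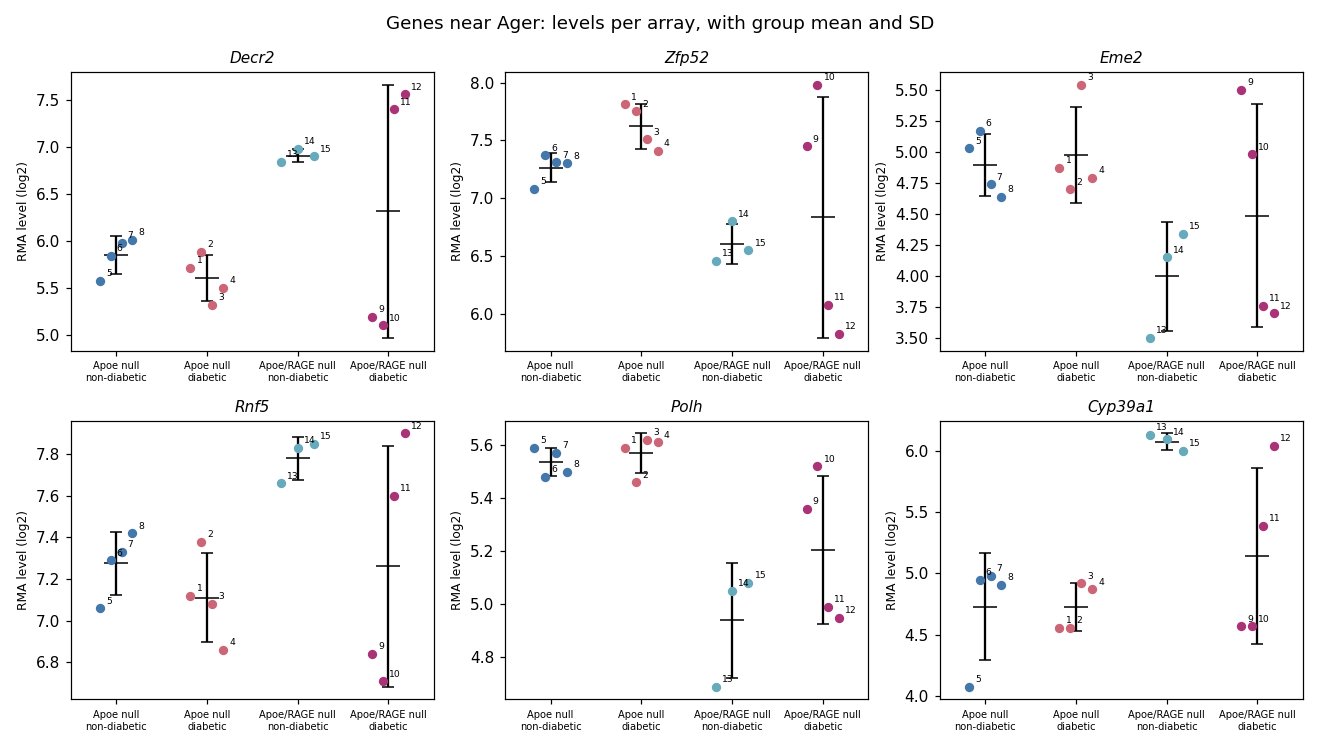
RMA level (log2, vertical axis) of 6 genes near Ager in the 4 groups (horizontal axis); points are single arrays with their replicate number, and bars give the group mean and SD. In Decr2, replicates 9 and 10 of the diabetic Apoe/RAGE null group sit at 5.19 and 5.10, with the Apoe null arrays, and replicates 11 and 12 at 7.40 and 7.56.

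The first comparison asked what diabetes does in the Apoe null aorta. Lipid synthesis genes were lower in diabetic mice. Of the 16 measured genes of lipogenesis and targets of its regulator SREBP1, 15 had negative fold changes, with a median log2 fold change of -1.11. Fasn, fatty acid synthase, fell by 2.33 ± 0.29 (SE) and Acaca, acetyl-CoA carboxylase, by 1.57 ± 0.27 when adjusted over the list alone, as did Thrsp (-1.16) and Me1 (-1.20). In all, 12 members fell when adjusted over the list alone and 0 when adjusted over all probe sets. The shift of the list passed camera (adjusted p = 8.6e-15), with adjusted p = 0.233 with an estimated correlation.

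Genes of protein folding were higher in the diabetic Apoe null aorta. Hsph1 (1.12 ± 0.19, SE), Hspa1b (1.27 ± 0.24) and Hspa1a (1.32 ± 0.32), all heat shock proteins, and Hspa5 (0.55 ± 0.14, with 2 of its 3 probe sets higher), the chaperone of the endoplasmic reticulum, were among 5 of 16 members of the heat shock list that rose when adjusted over the list alone, against 0 over all probe sets. The list passed camera (adjusted p = 4.7e-08; adjusted p = 0.233 with an estimated correlation). In the list of RAGE ligands and partners, S100a4 (0.88 ± 0.14, SE) and S100a6 (0.51 ± 0.12) rose and S100b (-0.86 ± 0.30) fell when adjusted over the list alone. Glo1, a listed enzyme that detoxifies methylglyoxal and is not itself a ligand, also fell by that adjustment (-0.57 ± 0.15). This list was chosen knowing the authors' interest and is not independent evidence, and as a whole it did not shift by camera in limma (adjusted p = 0.822).

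Energy and fat genes were lower in 3 of the 4 diabetic mice. In replicate 2 the scores of oxidative phosphorylation (0.16), fatty acid oxidation (0.16) and brown adipocyte genes (0.29) were not below the non-diabetic means of 0.11, 0.13 and 0.19. All 19 measured genes of mitochondrial oxidative phosphorylation had negative fold changes (median -0.45; camera adjusted p = 5.0e-09; adjusted p = 0.50 with an estimated correlation), though 0 passed singly. Fatty acid oxidation (10 of 16 fell when adjusted over the list alone; median -0.70), white adipocyte genes (6 of 11; median -0.57) and brown adipocyte genes (6 of 11; median -0.84) also passed camera downward, each with adjusted p = 0.50 with an estimated correlation. Examples were Hadha (-0.90) and Cpt2 (-0.92) of fatty acid oxidation, Cidec (-0.89) and Lipe (-1.04, with 1 of its 2 probe sets lower) of fat storage and breakdown, and Ucp1 (-1.06), the uncoupling protein of brown fat. Lists of immediate early genes (median 0.31), macrophages (0.32), skeletal muscle (1.18) and vascular inflammation (0.15) passed camera upward, with adjusted p between 0.50 and 0.735 with an estimated correlation. The difference in score of immediate early genes, 0.30, was 0.18 without diabetic replicate 3, and that of skeletal muscle, 1.13, was 0.62 without diabetic replicate 4 and 1.92 without non-diabetic replicate 8. Skeletal muscle and fat are not part of the vessel wall, and the group means of their lists differed with the diabetic label here. The skeletal muscle scores overlapped widely, from -1.40 to 1.70 in diabetic and from -2.08 to 1.42 in non-diabetic arrays. White adipocyte scores ranged from -0.66 to 0.05 in diabetic and from 0.01 to 0.25 in non-diabetic arrays.

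Over the 45037 probe sets, 0 passed limma at an adjusted p of 0.05 in this comparison, with 4791 at an unadjusted p under 0.05. Fasn came nearest (limma adjusted p = 0.0515). The submitters' own threshold of B above 0 took 76 probe sets, 47 higher and 29 lower. The genes with the next smallest p were S100a4, Dnaja1, Hsph1, Chordc1 and Tspan6 on the higher side and Eepd1, Acaca, Slc25a1 and Aacs on the lower side, with adjusted p between 0.205 and 0.222. Of the 18193 genes, 7.62% had non-overlapping values in the 2 groups, against 2.86% on average by chance. How far this share varies between splits of the arrays was not computed. Without non-diabetic Apoe null replicate 5 the limma count was 1.

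**Figure D2:**
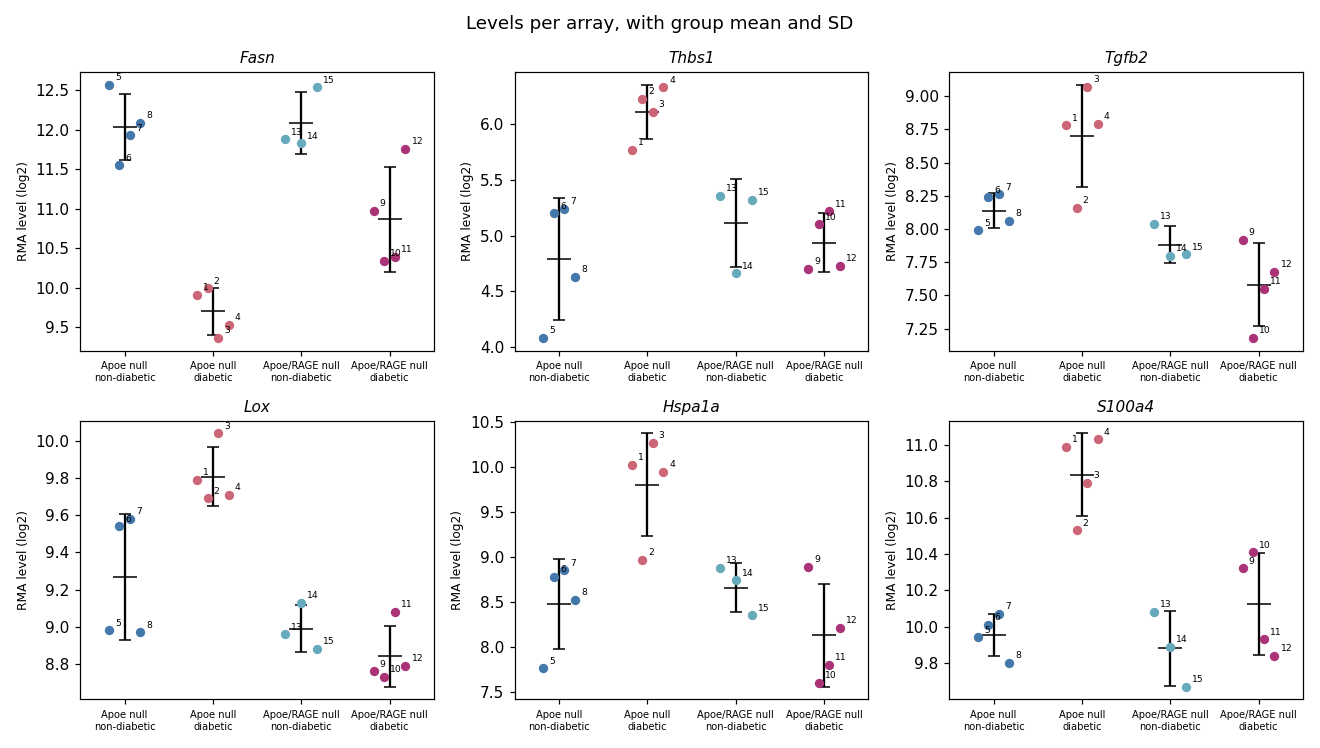
RMA level (log2, vertical axis) of 6 genes in the 4 groups (horizontal axis); points are single arrays with their replicate number, and bars give the group mean and SD. Fasn differs by -2.33 between diabetic and non-diabetic Apoe null aorta, and Tgfb2, Lox and Hspa1a by -1.12, -0.96 and -1.68 between diabetic Apoe/RAGE null and diabetic Apoe null aorta as labelled.

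The second comparison asked what RAGE deletion does without diabetes. No difference passed limma (0 probe sets; 1159 at an unadjusted p under 0.05; 0 with B above 0). Gsta3, a glutathione transferase gene (0.94 ± 0.21, SE), Cyp39a1 (1.34 ± 0.30), Camta1 (0.72 ± 0.17, with 3 of its 4 probe sets higher), Sarm1 (0.52 ± 0.12) and Enpp4 (0.44 ± 0.11) had the smallest p on the higher side, all with an adjusted p of 1. Polh, a DNA polymerase gene (-0.60 ± 0.13, with 1 of its 4 probe sets lower), Tcap (-1.07 ± 0.26), Abcc6 (-0.33 ± 0.09) and Lima1 (-0.37 ± 0.10, with 4 of its 5 probe sets lower) did so on the lower side. Cyp39a1, Enpp4 and Polh lie within 20 Mb of Ager, as do 13 of the 100 genes with the smallest p in this comparison (one-sided Fisher exact p = 1.49e-05). The Fisher test treats genes as independent, and splits of the arrays were not run for this number. The erythrocyte list shifted down by camera (5 of 5 negative, median -0.64; 2 of 5, Hbb-b2 and Alas2, fell when adjusted over the list alone), as did fibrillar matrix genes (18 of 23 negative, median -0.14). Cholesterol synthesis shifted up (13 of 14 positive, median 0.15). With an estimated correlation these lists had adjusted p = 0.544, 0.785 and 0.629. Camera also passed lists of matrix proteases (-0.10), vascular inflammation (-0.11), immediate early genes (-0.18), endothelium (-0.13), adventitial fibroblasts (-0.10), B and plasma cells (-0.52), neutrophils (-0.14) and skeletal muscle (-0.58) downward and of nerve (0.19) upward, with adjusted p between 0.544 and 0.851 with an estimated correlation. Single arrays carried much of several of these shifts. The difference in score of erythrocyte genes, -0.62, was -0.34 without Apoe null replicate 5, and that of B and plasma cell genes, -0.73, was -0.48. Matrix genes (-0.15) gave -0.10 without Apoe null replicate 6, -0.09 without replicate 7 and -0.04 without Apoe/RAGE null replicate 15. Cholesterol synthesis (0.17) gave 0.10 and nerve genes (0.55) 0.12 without Apoe/RAGE null replicate 13, and nerve genes 0.83 without replicate 14. Endothelium (-0.12) gave -0.06 without Apoe/RAGE null replicate 14 and -0.20 without replicate 15. Fibroblast genes (-0.13) gave -0.08 without Apoe null replicate 7 and -0.09 without Apoe/RAGE null replicate 15, and immediate early genes (-0.21) gave -0.14 without Apoe null replicate 6. Skeletal muscle (-0.69) gave -1.07 without Apoe null replicate 6, -1.06 without replicate 7, 0.10 without replicate 8 and -0.41 without Apoe/RAGE null replicate 14. In all 12 of 35 lists passed, 2 up and 10 down. Their number was 7 without non-diabetic Apoe null replicate 8, where the skeletal muscle list changed sign, and 6 without Apoe/RAGE null replicate 13. The share of genes with non-overlapping values, 4.87%, was below the 5.71% that chance gives for 4 against 3 arrays.

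The third comparison asked what diabetes does in the Apoe/RAGE null aorta. Markers of skeletal muscle and of blood cells were higher in the diabetic group. All 13 skeletal muscle genes had positive fold changes (median 3.93) and 11 rose when adjusted over the list alone, among them the muscle myosins Myh1 (5.29 ± 0.96, SE, with 2 of its 3 probe sets higher) and Myh2 (4.68 ± 0.93). The neutrophil genes S100a8 (2.64 ± 0.52) and S100a9 (2.32 ± 0.45), and the macrophage genes Cd68 (1.02 ± 0.28) and C1qb (0.91 ± 0.26), rose when adjusted over their lists alone, as did 5 of 10 neutrophil and 11 of 17 macrophage genes in all. Camera passed all 3 lists (adjusted p = 1.5e-21, 6.2e-06 and 5.3e-11), with adjusted p = 0.169, 0.147 and 0.172 with an estimated correlation. The interferon list, all 18 members of which were positive (median 0.40), and the endothelium list (12 of 14 positive, median 0.35) also passed camera upward, with adjusted p = 0.169 and 0.398 with an estimated correlation. The difference in score of macrophage genes, 0.58, was 0.37 without diabetic replicate 10.

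Lipogenesis genes were lower here too, though fewer passed. Fasn fell by 1.22 ± 0.32 (SE) and Me1 by 1.05 ± 0.28 when adjusted over the list alone, 2 of 16 members (median -0.53; camera adjusted p = 0.0041; adjusted p = 0.527 with an estimated correlation). Fibrillar matrix (20 of 23 negative, median -0.23), cholesterol synthesis (12 of 14 negative, median -0.21) and smooth muscle contractile genes (14 of 15 negative, median -0.21) passed camera downward, with adjusted p between 0.398 and 0.595 with an estimated correlation. Lists of class II (0.94) and class I (0.22) antigen presentation, B and plasma cells (1.24), T and NK cells (0.55), the cell cycle (0.20), vascular inflammation (0.13), foam cells (0.09), RAGE ligands (0.04) and cardiac muscle (0.29) passed camera upward, with adjusted p between 0.169 and 0.626 with an estimated correlation. The RAGE ligand list, with its median near 0, holds S100a8 (2.64) and S100a9 (2.32), which are also in the neutrophil list. How many members of the class II, class I and interferon lists lie within 20 Mb of Ager was not counted. Replicate 10 carried much of these list shifts. Without it the difference in score went from 0.87 to 0.29 for class II, from 0.25 to 0.07 for class I, from 1.31 to 0.53 for B and plasma cells, from 0.60 to 0.05 for T and NK cells, from 0.25 to 0.06 for the cell cycle, from 0.27 to 0.15 for vascular inflammation and from -0.40 to -0.27 for lipogenesis. Without replicate 11 it went from 0.85 to 0.56 for cardiac muscle, from 0.21 to 0.14 for foam cells and from -0.19 to -0.09 for smooth muscle. Without non-diabetic replicate 13 it was 0.12 for foam cells, -0.13 for cholesterol synthesis (-0.20 with it), -0.14 for matrix (-0.21 with it) and -0.12 for smooth muscle. It was 0.49 for cardiac muscle without replicate 14 and -0.19 for lipogenesis without replicate 15. Limma passed 0 probe sets, with 3269 at an unadjusted p under 0.05 and 4 with B above 0. The smallest p belonged to the airway secretory gene Scgb1a1 (4.99 ± 0.84, SE; limma adjusted p = 0.457). Without replicates 9 and 10 the count was also 0, and without replicate 12 it was 49. Of the 35 lists 18 passed camera, and 18 without replicates 9 and 10.

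The fourth comparison asked what RAGE deletion does in diabetes, and it was the one in which single genes passed. Of the probe sets, 110 passed limma, 12 higher and 98 lower in the diabetic group labelled Apoe/RAGE null. Lower were Tgfb2, a TGF-beta ligand (-1.12 ± 0.18, SE), Lox, which crosslinks collagen and elastin (-0.96 ± 0.14), the Wnt inhibitors Wif1 (-1.55 ± 0.24) and Sfrp2 (-1.20 ± 0.21), the growth factor gene Ereg (-1.52 ± 0.23), the histone deacetylase gene Hdac9 (-1.05 ± 0.18), and Hspa1a (-1.68 ± 0.32). Scube3 (-1.45), Klhl30 (-1.23), Tnfrsf12a (-1.22), Stum (-1.20), Efhc2 (-1.07) and Ptprz1 (-0.99) also fell. Higher were Erdr1 (1.96 ± 0.30), the acyl-CoA thioesterase gene Acot1 (1.26 ± 0.23), Glo1 (0.81 ± 0.15), Rgs17 (0.56 ± 0.09) and Eepd1 (0.52 ± 0.10). The adjusted p of these genes lay between 0.0356 and 0.0469. Glo1, Scube3, Tnfrsf12a and Hspa1a lie within 20 Mb of Ager. Without diabetes the Apoe/RAGE null and Apoe null means were 9.40 and 9.09 for Glo1 but 8.18 and 8.21 for Scube3, 8.22 and 8.21 for Tnfrsf12a and 8.66 and 8.48 for Hspa1a. Of the 100 genes with the smallest p in this comparison 5 lie there, against 3.14% of all genes (one-sided Fisher exact p = 0.207).

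Extracellular matrix genes were lower as a group. All 23 fibrillar matrix and elastic fibre genes had negative fold changes (median -0.42), 18 fell when adjusted over the list alone and 1 when adjusted over all probe sets. Besides Lox these included Eln, elastin (-0.90 ± 0.20, SE), Col5a2 (-0.72 ± 0.14) and Mfap5 (-0.60 ± 0.13). Camera gave adjusted p = 5.8e-12, with adjusted p = 0.293 with an estimated correlation. Heat shock genes (16 of 16 negative, median -0.26) and immediate early genes (17 of 17 negative, median -0.48) passed camera downward, both with adjusted p = 0.293 with an estimated correlation. Smooth muscle contractile genes (14 of 15 negative, median -0.31) did too, with adjusted p = 0.387 with an estimated correlation.

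Lipid and energy genes were higher in the group mean. All 16 lipogenesis genes were positive (median 0.69), and 7 rose when adjusted over the list alone and 0 over all probe sets, including Acacb (1.44 ± 0.35, SE) and Fasn (1.16 ± 0.29). The list passed camera (adjusted p = 2.06e-07), with adjusted p = 0.293 with an estimated correlation. Oxidative phosphorylation (19 of 19 positive, median 0.42), fatty acid oxidation (15 of 16, median 0.64), white adipocyte (11 of 11, median 0.55) and skeletal muscle genes (13 of 13, median 2.01) passed camera upward, with adjusted p between 0.294 and 0.359 with an estimated correlation. Foam cell (0.36), interferon (0.28), T and NK cell (0.52), neutrophil (0.35), brown adipocyte (0.72), glucocorticoid (0.32), macrophage (0.20) and B and plasma cell genes (0.61) passed upward too, and matrix proteases (-0.25) and fibroblast genes (-0.20) downward, with adjusted p between 0.293 and 0.568 with an estimated correlation. In replicates 9 to 12 oxidative phosphorylation scored -0.124, -0.264, 0.389 and 0.36 and fatty acid oxidation -0.077, -0.359, 0.582 and 0.516. Lipogenesis scored -0.117, -0.401, 0.097 and 0.443. In replicates 9 and 10 both energy scores were below those of diabetic Apoe null replicate 2 (0.162 and 0.165). So was lipogenesis in replicate 10 (-0.19 in replicate 2). All these scores were above those of diabetic Apoe null replicates 1, 3 and 4. Without replicate 10 the difference in score went from 0.70 to -0.08 for B and plasma cells, from 0.18 to -0.03 for macrophages, from 0.59 to 0.04 for T and NK cells, from 0.29 to 0.15 for interferon and from -0.21 to -0.13 for fibroblasts. For B and plasma cells it was 1.06 without replicate 9 and 1.07 without replicate 12, and for macrophages 0.36 without replicate 12 and 0.11 without diabetic Apoe null replicate 3. The group means of fat and skeletal muscle markers thus moved beside those of the lipid genes, though single arrays of the groups overlapped, as the plot of tissue marker scores shows.

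The count of this comparison depended on single arrays and on the fit. It was 0 when diabetic Apoe null replicate 1, 3 or 4 was left out, and 931 without diabetic Apoe null replicate 2. In the Apoe/RAGE null group it was 24 without replicate 9, 2 without replicate 10, 1 without replicate 11 and 31 without replicate 12, and 22 without replicates 9 and 10 together. Of the 35 lists 20 passed camera, and 14 without replicates 9 and 10. The count of probe sets was 0 when only the 2 compared groups entered the fit. Each other comparison of 2 groups then had calls, so which comparison has calls depends on the fit. The count was also 0 with tissue scores as covariates. With these covariates the median of the 52 lower genes went from -0.80 to -0.56 (the median of the single genes' SE was 0.14 in both fits) and all 52 stayed negative. The fold shrank, and the covariates also took residual degrees of freedom. Which of these ended the calls was not tested. Of the 18193 genes, 7.73% had non-overlapping values in the 2 groups, against 2.86% on average by chance. Its variation between splits of the arrays was not computed either.

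**Figure D3:**
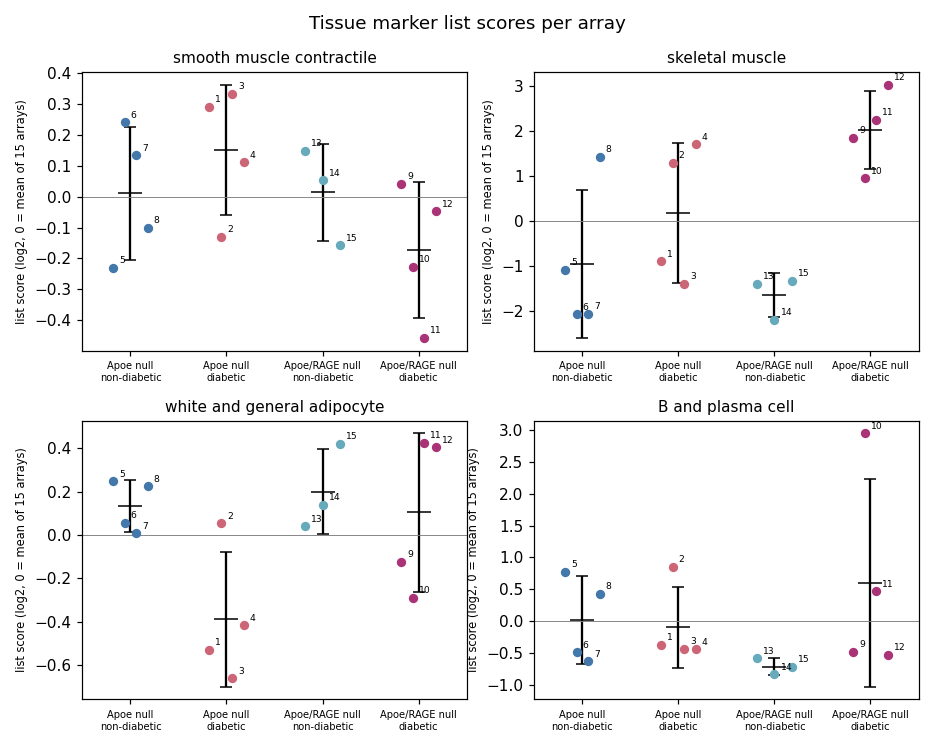
Mean level of 4 marker lists per array (log2, vertical axis, relative to the mean of the 15 arrays) in the 4 groups (horizontal axis); points are single arrays with their replicate number, and bars give the group mean and SD. The skeletal muscle score is above 0 in all 4 diabetic Apoe/RAGE null arrays, from 0.95 to 3.02, and the B and plasma cell score reaches 2.95 in replicate 10.

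The interaction asked whether diabetes acted differently in the 2 genotypes. No probe set passed limma (0; 3251 at an unadjusted p under 0.05; 0 with B above 0), so no single gene was shown to respond differently. By camera 20 of 35 lists passed, 15 up and 5 down, and 0 with an estimated correlation (smallest adjusted p = 0.376). The interaction of Fasn was 1.11 ± 0.43 (SE) and did not pass (limma adjusted p = 0.675). The interactions of Hspa1a (-1.86 ± 0.47), Hspa1b (-1.39 ± 0.36) and S100a9 (2.25 ± 0.61) passed when adjusted over their lists alone. Hspa1a and Hspa1b were higher with diabetes in Apoe null aorta (1.32 and 1.27), and both lie within 20 Mb of Ager. The smallest p over all genes belonged to Eepd1, Ngp and Tbx1 on the higher side and Tshz3, Ereg and Pip5k1b on the lower side, all with a limma adjusted p = 0.675. Without replicates 9 and 10 the count of probe sets was 0 and that of lists 14. The lists that passed and are reported here are given with their medians in the closing section. Lists that passed in no comparison were calcification (median 0.08 with diabetes in Apoe null aorta), insulin signalling (-0.07), oxidative stress (0.06), the circadian clock (-0.02) and lymph node stroma (0.29). The median and the direction of camera differed in sign for 3, 5, 8, 3 and 0 lists in the 5 comparisons in the order given here.

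Across the 18193 genes, which are not independent replicates, the fold changes of diabetes in the 2 genotypes correlated with Pearson's r = 0.271 and a Spearman correlation of 0.130. In 100 simulations of unchanged groups made from the arrays' own residuals r ranged from -0.574 to 0.640, and 22 reached the observed value. The covariance, 0.0172, was reached by 4. RAGE deletion with and without diabetes gave r = 0.211 and a Spearman correlation of 0.0619, and 27 of the 100 simulations reached that r and 14 its covariance of 0.0111. The correlations were thus within what the spread between arrays gives, and the covariance of the diabetes effects was near its upper end.

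The fold changes of diabetes in Apoe null and of RAGE deletion in diabetic aorta were opposite in sign for 71.0% of genes (r = -0.465). Both comparisons share the 4 diabetic Apoe null arrays with opposite signs, and unchanged groups gave 66.9% and a mean r of -0.510. The covariance was -0.0308 against -0.0191 in the simulations, and 17 of the 100 were at or beyond it. With 2 of the shared arrays given to each comparison, r averaged -0.251 and ranged from -0.453 to 0.0160. No gene could pass both tests in opposite directions, since 0 passed limma for diabetes in Apoe null aorta, so that count decides nothing. At B above 0 there were 12 such genes, 10 higher with diabetes and lower with RAGE deletion and 2 the other way. Without replicates 9 and 10 there were 13. The 12 included Thbs1, S100a4, Hspa1b, Hsph1, Dnaja1 and Chordc1. The shared arrays alone favour such pairs, and the number they give without any effect was not computed.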

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

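The splits of the arrays for counts of probe sets and the test of genes called in both RAGE comparisons were planned; the splits for counts of lists and the other tests in this part were chosen after the result was seen.

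Single arrays stood far from the rest of their group in 4 of 102 groups of list scores and 15 of 206 groups of gene levels, where chance gives about 5%. The list scores were vascular inflammation in non-diabetic Apoe null replicate 6 (-0.03), cell cycle in diabetic Apoe/RAGE null replicate 10 (0.69), B and plasma cell in diabetic Apoe null replicate 2 (0.85), and cardiac muscle in diabetic Apoe/RAGE null replicate 11 (1.15). Diabetic Apoe null replicate 2 stood apart in 6 genes, Hspa1b (10.63), Cidec (9.54), Cpt2 (9.80), Slc2a4 (8.65), Wif1 (7.16) and Kdr (6.8), and replicate 1 in Selp (6.43). In non-diabetic Apoe null aorta replicate 7 stood apart in Ngp (3.98) and replicate 5 in Cyp39a1 (4.08). In diabetic Apoe/RAGE null aorta replicate 12 stood apart in Ryr1 (6.37) and Egfl7 (7.07), replicate 10 in Camta1 (6.25), Klhl30 (5.58) and Stum (6.59), and replicate 9 in Hspa1b (10.65).

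The effect of diabetes differed between the genotypes by camera on the interaction for 20 lists, and for 0 with an estimated correlation. Of those reported here, medians were negative for fibrillar matrix (-0.26), heat shock (-0.24), immediate early genes (-0.28) and smooth muscle (-0.36). They were positive for interferon (0.23), class II presentation (0.63), fatty acid oxidation (0.58), lipogenesis (0.67), foam cells (0.38), oxidative phosphorylation (0.34), endothelium (0.38), macrophages (0.36), T and NK cells (0.56), B and plasma cells (1.22), neutrophils (0.56), erythrocytes (0.53), white adipocytes (0.38), brown adipocytes (0.69) and skeletal muscle (2.65). How many members of the class II and interferon lists lie within 20 Mb of Ager was not counted, so a share of linked genes in their shifts stays open. Several of the lists rested on diabetic Apoe/RAGE null replicate 10. Without it the interaction of the score went from 0.62 to 0.04 for class II, from 0.62 to 0.07 for T and NK cells, from 1.43 to 0.65 for B and plasma cells, from 0.29 to 0.08 for macrophages and from 0.29 to 0.15 for interferon. Without replicate 12 it was 0.95 for class II, 0.46 for macrophages and -0.22 for immediate early genes (-0.33 with it), which gave -0.21 without diabetic Apoe null replicate 3. Without Apoe/RAGE null replicate 13 it went from 0.35 to 0.21 for oxidative phosphorylation and from 0.61 to 0.37 for brown adipocytes, and without Apoe null replicate 5 from 0.42 to 0.14 for erythrocytes.

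Splits of the same arrays into groups of the same sizes, counted here with the real one included, do not exclude chance for the counts below that are above 0. For RAGE deletion in diabetes 2 of 35 splits gave at least the real 110 probe sets, the real one and 1 other, which gave 514. That other split set diabetic Apoe null replicates 1, 3 and 4 with Apoe/RAGE null replicate 9 against the rest. These 4 had the highest scores of heat shock and immediate early genes among the 8 diabetic arrays (0.30, 0.53, 0.49 and 0.10, against 0.03 in the next). A real limma count of 0 is met by every split and decides nothing, as by 35 of 35 for diabetes in Apoe null aorta (highest other 0), in Apoe/RAGE null aorta (highest other 459, with replicate 12 set among the non-diabetic arrays) and for RAGE deletion without diabetes (highest other 0), and by 100 of 100 for the interaction (highest other 90). The numbers of probe sets at an unadjusted p under 0.05 in these comparisons, 4791, 3269, 1159 and 3251, were reached by 4, 10 and 24 of 35 and by 16 of 100 splits. For lists, 16 of 35 splits (real 11, highest other 20), 8 of 35 (12 and 16), 4 of 35 (18 and 20), 6 of 35 (20 and 22) and 6 of 100 (20 and 22) gave as many, in the order diabetes in Apoe null, RAGE deletion without diabetes, diabetes in Apoe/RAGE null, RAGE deletion with diabetes, and interaction.

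The first pattern weighed was the 52 genes lower in diabetic Apoe/RAGE null than in diabetic Apoe null aorta. Genes picked on 2 arrays per group fell further on the others (median -0.70) than smooth muscle (-0.28) and fibroblast lists (-0.20) in 36 of 36 ways of dividing the groups, but the lowest of all genes would pass the median of an unselected list under most causes, so a smaller share of vessel wall stays open. With a score of heat shock and immediate early genes as a covariate, which stands for stress in handling, the median of the 50 genes outside those lists went from -0.79 to -0.49. The median of the single genes' SE went from 0.14 to 0.19, and 0 passed. Part of the pattern may come from such stress, and what ended the calls was not tested. An exchange of labels between diabetic Apoe null replicate 2 and Apoe/RAGE null replicate 9 needs replicate 2 to read as RAGE null, and on genes near Ager both it (score -0.145) and replicate 9 (-0.251) read like the other diabetic Apoe null arrays (mean -0.196), as did replicate 10 (-0.264), labelled RAGE null, so a low score does not show the genotype and the exchange stays open. Chance (2 of 35 splits, the real one included), the different colonies and an effect of RAGE also stay open.

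The second pattern was the lower lipogenesis genes in diabetic Apoe null aorta. The lipogenesis score fell further than the white adipocyte score, by -0.54 (exact permutation p = 0.0286, the smallest that 70 labelings allow). The scores themselves differed by -1.06 and -0.52. The lipogenesis list was taken up after its fall was seen and was set against the white adipocyte list only. The brown adipocyte score, 0.19 without and -0.50 with diabetes, was not used, so less fat tissue stays open. Both scores may share a cause, and an effect of diabetes on the lipogenesis genes also stays open and was not tested apart from the other causes.

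The third pattern was in genes near Ager, where the planned test had 0 genes called in both comparisons and decides nothing. Of the 100 genes with the smallest p for RAGE deletion averaged over both disease states, 9 lay within 20 Mb of Ager against 3.14% of all genes (one-sided Fisher exact p = 0.00425), and 4 of 100 splits gave as many (highest other 13), so a genome segment carried along with the deleted gene may explain them. Over 567 genes near Ager, the arrays labelled diabetic Apoe/RAGE null followed the genotype difference of the non-diabetic arrays with r = 0.396 and 0.563 in replicates 11 and 12 but -0.00019 and -0.155 in replicates 9 and 10, within and below the range of the diabetic Apoe null arrays (-0.0930 to 0.145). Over genes elsewhere replicates 11 and 12 also followed it (0.246 and 0.238, against 0.0532 and 0.0798 in 9 and 10), so the contrast is not confined to the segment, in which the 20 genes nearest Ager gave -0.105, -0.197, 0.154 and 0.424 in replicates 9 to 12 and up to 0.160 in diabetic Apoe null arrays. Wrong labels of replicates 9 and 10, and mice in which this segment was not fixed, stay open; either bears on each comparison that uses the diabetic Apoe/RAGE null group.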

How the results depend on the processing

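The settings that left out the 2 arrays least like the rest or diabetic Apoe/RAGE null replicates 9 and 10, that used tissue scores as covariates, and B above 0 for opposite changes were chosen after the data were seen. Of the counts of probe sets, of lists and of genes with opposite changes, 149 stayed within 1.5 times the reported count and 47 did not. A reported 0 that stayed 0 is among the 149, as for the probe sets of the interaction with each array left out in turn. Unless stated, the cause of a move was not tested.

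With B above 0 as the threshold, diabetes gave 76 probe sets in Apoe null and 4 in Apoe/RAGE null aorta, RAGE deletion in diabetes gave 321, and 12 genes changed in opposite directions (13 without replicates 9 and 10). With only the compared groups in the fit the counts were 5 and 12 for diabetes in the 2 genotypes, and 5 without and 0 with diabetes for RAGE deletion. For RAGE deletion in diabetes, reported as 110, the count was 253 without the dimmer probe sets, 53 with array weights, 72 with 1 probe set per gene (fewer tests), 4 without the 2 arrays least like the rest, 22 without replicates 9 and 10, and 0 with tissue covariates. Quantile normalization, median centring and a trended robust variance gave 113, 153 and 114. For diabetes in Apoe null aorta, reported as 0 by limma (4791 at an unadjusted p under 0.05), the count was 1 without the dimmer probe sets, 1 with quantile normalization, 7 with array weights, 1 with 1 probe set per gene, 1 without probe sets that can share probes, and 2 without the 2 arrays. Array weights gave 2 genes with opposite changes.

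With arrays left out in turn the counts ranged from 0 to 1 for diabetes in Apoe null aorta, from 0 to 49 in Apoe/RAGE null aorta, from 0 to 931 for RAGE deletion in diabetes and from 0 to 1 for opposite changes. The value 49 came without diabetic Apoe/RAGE null replicate 12 and 931 without diabetic Apoe null replicate 2. The number of lists ranged from 9 to 13 and 14 to 19 for diabetes in the 2 genotypes, from 6 to 13 and 17 to 22 for RAGE deletion without and with diabetes, and from 14 to 21 for the interaction. The correlations of fold changes ranged from 0.137 to 0.382 and from 0.0577 to 0.354. The Ager level kept its sign in every setting run and did not pass in any.

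An estimated correlation left 0, 0, 0, 0 and 0 lists in the 5 comparisons, and fry passed 2, 0, 0, 7 and 0, of which 8 lists had passed camera. Without the 2 arrays 9 lists passed for diabetes in Apoe/RAGE null aorta and 12 for the interaction. The direction, 1 for up and -1 for down, reversed without those arrays to -1 for class I presentation and T and NK cells with diabetes in Apoe/RAGE null aorta, for macrophages and B and plasma cells with RAGE deletion in diabetes, and for class II presentation and macrophages in the interaction. Of these only the macrophage list with RAGE deletion in diabetes passed camera in its new direction (adjusted p = 0.0265), where 8 lists passed up and 10 down against 13 and 7 as reported. It reversed to -1 for macrophages and B and plasma cells with RAGE deletion in diabetes without diabetic Apoe/RAGE null replicate 10, and to 1 for skeletal muscle with RAGE deletion without diabetes when non-diabetic Apoe null replicate 8 was left out. With tissue covariates, built from fat and muscle genes, the fold changes of Lipe (0.00051), Ucp1 (0.045), Hadha (0.052) and Cpt2 (0.092) with diabetes in Apoe null and of Myh1 (-0.15) and Myh2 (-0.14) in Apoe/RAGE null aorta reversed. Of single named genes 201 values became weaker and 45 stronger over the settings, and 2141 kept direction and side of the threshold. As reported 19 of the 141 named values passed, so the others count as kept where they stayed short of the threshold.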

Other observations

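The tissue covariate tests in this part were chosen after the result was seen. With scores of smooth muscle, white adipocyte and skeletal muscle lists as covariates, the 52 genes lower in diabetic Apoe/RAGE null aorta kept 70.2% of their median fold change (-0.80 before and -0.56 after, where the median of the single genes' SE was 0.14 both times), and 0 passed. Of RAGE deletion alone without diabetes, 13 of the 100 genes with the smallest p lay within 20 Mb of Ager (one-sided Fisher exact p = 1.5e-05), and with diabetes 5 did (exact p = 0.207). For diabetes the numbers were 3 in Apoe null and 2 in Apoe/RAGE null aorta. The Fisher test treats genes as independent, and splits of the arrays were not run for these numbers.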
